A study of Homo sapiens with 16 samples.

How the data were processed

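The data are 16 arrays of naive CD4+ T cells from 4 patients with chronic lymphocytic leukemia, 4 arrays for each of 4 groups: control or 1 µM pevonedistat, at 3 h or 24 h of stimulation. Per the labels' protocols, a few nanograms of total RNA per sample were amplified and labelled with biotin before hybridisation. The deposited table holds 1 value per array feature and array, on the log2 scale with 2 decimals, between 1.99 and 18.76; that the unit is log2 signal was read from the range of these deposited values. The submitters' processing notes name Transcriptome Analysis Console 4.0. The background correction, the summary of probes and the normalization between arrays are not given in the sources used here. Medians lay between 5.51 and 5.6 and upper quartiles between 8.36 and 8.51, so the arrays were already on a common scale, and the values were used as deposited. Amplification from little RNA can add noise and compress folds, and signals near the lower end hold little information; no detection call or scanner file was used here. A log2 fold change between groups is a relative one, since arrays brought to a common scale cannot show a change in the total RNA of a cell.

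The table has 21448 features. Through the platform annotation, 17709 had 1 gene symbol, 0 had several and 3739 had none; all 17709 matched the reference table of assembly GRCh38.p14 by gene identifier, and 0 symbols changed. That table was used for names only, and no coordinate is given since the build of the array's annotation was not stated. Features of genes on chromosome Y, of XIST and TSIX, of HLA genes and of GSTM1 and GSTT1, 93 in all, were left out of every table because they can carry information on a person. Where a gene had more than 1 feature (17 genes), the feature with the highest mean over all arrays was used; in 10 of these genes the features differed in sign at 24 h, and none of them is named. This left 17647 genes.

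Groups were taken from the labels, and each group holds patients 1 to 4. The main test was a limma (3.58.1, R 4.3.3) linear model with 1 mean per group over all 16 arrays and moderated variances, with 12 residual and 4.91 prior degrees of freedom. There were 5 contrasts: pevonedistat against control at 3 h and at 24 h, the difference of these effects, and 24 h against 3 h in control and in pevonedistat cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. All p-values are two-sided. The same patients gave arrays to every group per the labels, so the numbers pair the samples. Deviations from the group means of arrays of the same patient correlated with a median of 0.117 (0.0421 to 0.216 over 24 pairs of arrays), against a median of -0.0377 for different patients in different groups, and 16 of 16 arrays correlated best with another array of the same patient. The fit with the patient as a block was an alternative. Arrays of the same group correlated between 0.9606 and 0.9846, with no sign of a repeated array. The first principal component held 31.1% of the variance and separated 3 h from 24 h. The second held 9.63% and placed patients 1 and 2 above patients 3 and 4 in every group. No batch or scan information was in the sources used here.

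Before the data were examined, the tests, the lists and the rule for naming genes were fixed. The 35 gene lists were written from textbook knowledge: pathways, T cell states, targets of substrates of cullin-RING ligases, and markers of other blood cells. They hold 753 genes, of which 682 were measured. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 35 lists within a contrast, and beside it with an estimated correlation, with fry and with the patient as a block. With the preset correlation camera called 5 lists at 3 h, 17 at 24 h, 18 between the times in control cells and 12 between the times in pevonedistat cells; with an estimated correlation it called 2, 11, 11 and 8. A list's members were also adjusted over the list alone. Where the same gene is in several lists (LTA, IL2RA), the lists are not independent. For each pevonedistat contrast, the naming rule took the 10 largest rises and 10 largest falls among called genes with the same direction in all 4 patients. For the other contrasts it took the 5 largest each way. From each described list it took up to 4 members with the smallest adjusted p, and the genes that head a list (CDKN1A, NFKBIA, NQO1, FOXP3, TBX21, IFNG, GATA3, IL2, MKI67, NAE1 and UBA3) whatever their test. Predicted loci and immunoglobulin and T cell receptor segments were passed over. IL23A was named outside the rule, after its values were seen.

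The fit was tested on simulated data drawn from the real means and standard deviations of 17647 genes with 200 changed genes, 50 of each size. For the comparison at 3 h it called 0% of the genes changed by 0.5 on the log2 scale, 38% at 1, 90% at 2 and 98% at 3, with 5 unchanged genes called. For the comparison at 24 h it called 4%, 34%, 82% and 98%, with 2 unchanged genes called. A list of 25 genes shifted by 0.5 was called in both, and 0 lists were called without a shift. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes wrongly. In the other splits of the real arrays, which can hold part of any drug or patient difference, camera called a median of 2 lists at 3 h and 6.5 at 24 h. Alternatives were the patient as a block, only the 8 arrays compared, quantile normalization, arrays centred on their medians, leaving out the dimmest 0.333 of genes, eBayes with trend and robust settings, array weights, thresholds with a minimum fold of 2, every feature tested, the mean of a gene's features, and leaving out each patient and each array. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.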

Results

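Gene expression was measured by array in T cells sorted from the blood of 4 patients with chronic lymphocytic leukemia, a cancer of mature B cells. The sort took viable CD4+CD45RA+CD45RO- lymphocytes, the surface pattern of naive helper T cells, and the cells were used on the day the blood was taken. They were stimulated with 0.5 µg/ml antibody against CD3 and CD28, which engages the T cell receptor complex and its main costimulatory receptor. At the same time they received 1 µM pevonedistat or the solvent DMSO as control. Pevonedistat inhibits the enzyme that activates NEDD8, a ubiquitin-like protein whose attachment to cullins switches on the cullin-RING ubiquitin ligases. RNA was taken at 3 h or 24 h, which gave 4 groups of 4 arrays, 16 arrays in all, with the same 4 patients in each group. The median log2 signal of the arrays lay between 5.51 and 5.6, and 17647 genes were tested. Values below are log2 fold changes with their standard error from the fit over all arrays, or mean ± SD over the 4 arrays of a group. The number of arrays limits the precision: the median standard error of a comparison of 4 with 4 arrays was 0.284 on the log2 scale.

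What pevonedistat changed after 3 h was asked first. Targets of NF-kB, the transcription factor that the cullin-RING ligase substrate IkB alpha holds in the cytoplasm, were lower as a group with pevonedistat at 3 h. Their mean log2 fold change was -0.739 ± 0.205 (SD over the 4 patients) over 25 measured members, and it was negative in 4 of 4 patients (camera, adjusted p = 1.19e-10, and adjusted p = 0.0213 with an estimated correlation). Targets of NRF2, the transcription factor of the oxidative stress response, were higher as a group, with a mean of 0.461 ± 0.148 over 25 members in 4 of 4 patients (adjusted p = 5.89e-06, and adjusted p = 0.0322 with an estimated correlation). No single gene passed the threshold over all genes tested in the limma fit, where 929 genes had an unadjusted p under 0.05 and 882 were expected by chance. With the patient as a block 1 gene passed, TXNRD1 (thioredoxin reductase), with an adjusted p of 0.0252, and with trend and robust settings 1 gene passed. The smallest adjusted p without the block was 0.0856, for IL23A, an interleukin subunit named here after its value was seen, whose log2 fold change was -1.64 (SE 0.25).

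Within the lists fixed in advance, 5 of the 25 NF-kB targets were lower at 3 h when adjusted over the list alone. They were CD83, a surface protein of activated lymphocytes, at -2.23 (SE 0.38), NFKBIA, which encodes IkB alpha, at -1.86 (SE 0.32), NFKB2 at -1.66 (SE 0.34), NFKB1 at -1.50 (SE 0.42) and the cytokine gene LTA at -1.82 (SE 0.55). Of the NRF2 targets, 4 were higher when adjusted over the list alone. TXNRD1 stood at 1.60 (SE 0.26), the pentose phosphate enzyme TALDO1 at 1.98 (SE 0.46), thioredoxin (TXN) at 1.22 (SE 0.30) and glutathione reductase (GSR) at 0.95 (SE 0.26), while NQO1 was at -0.08 (SE 0.41). The lists of IL-2 and STAT5 targets (mean -0.337), early activation genes (mean -0.385) and cytokines and chemokines (mean -0.377) were also called lower by camera with its preset correlation. These 3 calls were lost when the correlation was estimated, with adjusted p = 0.448, adjusted p = 0.741 and adjusted p = 0.708. Of the IL-2 and STAT5 targets, 3 were lower when adjusted over the list alone, the receptor chains IL2RB at -1.47 (SE 0.28) and IL2RA at -1.67 (SE 0.36) and LTA. Of the early activation genes there were 2, IL2RA and the phosphatase DUSP5 at -1.83 (SE 0.45). KLF3, a transcription factor of resting T cells, was the 1 member of the naive and quiescence list that was higher when adjusted over its list alone, at 0.84 (SE 0.22). The genes of the drug's target, NAE1 and UBA3, were at 0.53 (SE 0.40) and -0.13 (SE 0.27) at 3 h. IL2 was at -1.0 (SE 0.68) and IFNG at 0.66 (SE 1.59, and 0.49 with the patient as a block). None of these 4 passed (adjusted p = 0.995, 0.999, 0.995 and 0.999). The other 30 of the 35 lists were not called at 3 h.

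After 24 h the same comparison showed a far-reaching loss of cytokine and NF-kB target transcripts. LTA (lymphotoxin alpha, array feature TC0600007595.hg.1) fell from a log2 signal of 16.54 ± 0.13 in control cells to 10.58 ± 1.38 with pevonedistat, which is 62.0-fold lower (adjusted p = 2.06e-05). The chemokine genes CXCL10 and CXCL9 were at least 54.0-fold and 26.8-fold lower, with log2 fold changes of -5.75 (SE 0.77) and -4.74 (SE 0.43). With pevonedistat CXCL10 stood at 4.83 and CXCL9 at 3.94, below the array medians and near the lower quartiles of 4.02 to 4.19, so these are lower bounds. The same holds for SDC4 (4.17), DTL (3.75), TNFRSF4 (4.3), LIF (4.6) and CAD (4.73) below. NFKBIA was 10.5-fold lower, at -3.39 (SE 0.32), and CD83 was 11.5-fold lower, at -3.52 (SE 0.38). In all, 159 genes passed the limma test with Benjamini-Hochberg adjustment, 61 of them higher and 98 lower with pevonedistat. With the patient as a block 302 genes passed, 130 higher and 172 lower, and 155 genes passed in both fits. The count fell to between 31 and 64 when the arrays of any 1 patient were left out. It fell to 84, 94, 100 and 101 without the 24 h control array of replicate 1, 2, 3 or 4, and to 90 and 92 without the 24 h pevonedistat array of replicate 2 or 3.

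The NF-kB list had the lowest p of all lists at 24 h. Of its 25 measured members 8 fell over all genes tested, and 14 were lower when adjusted over the list alone. LTB, the partner of lymphotoxin alpha, fell by 2.60 (SE 0.35). The list mean was -1.433 ± 0.284 (SD over the 4 patients). Camera gave an adjusted p of 7.85e-17, and of 0.00304 with an estimated correlation. Of 27 members of the cytokine and chemokine list, 7 were lower over all genes and 10 adjusted over the list alone. The list moved by a mean of -1.549 ± 0.175 (adjusted p = 1.26e-12, and adjusted p = 0.00893 with an estimated correlation). Beside those named above it held TNFSF14, also called LIGHT, which fell by 4.28 (SE 0.59). IL2, the growth factor gene of T cells, had a log2 fold change of -2.0 (SE 0.68), was lower in 4 of 4 patients and did not pass the test (adjusted p = 0.236). Targets of IL-2 and STAT5 had a mean of -1.097 ± 0.250 (adjusted p = 7.79e-12, and adjusted p = 0.00582 with an estimated correlation). Of 24 members 5 were lower over all genes and 7 adjusted over the list alone. Among them the survival gene BCL2L1 fell by 2.40 (SE 0.37), the high-affinity receptor chain IL2RA by 2.33 (SE 0.36) and the cytokine gene LIF fell by 2.44 (SE 0.39). The early activation list had a mean of -0.792 with 4 of 28 members lower over all genes and 7 adjusted over the list alone, which included the nuclear receptor NR4A3, down by 2.26 (SE 0.30), and the costimulatory receptor TNFRSF4 (OX40), down by 2.11 (SE 0.36). Its call was lost with an estimated correlation (adjusted p = 0.118). The remaining large falls were those of CD82, a tetraspanin, by 4.26 (SE 0.34), SLC43A3 by 3.81 (SE 0.52), SDC4 (syndecan-4) by 3.72 (SE 0.32) and IER3, an early response gene, by 3.16 (SE 0.54).

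**Figure D1:**
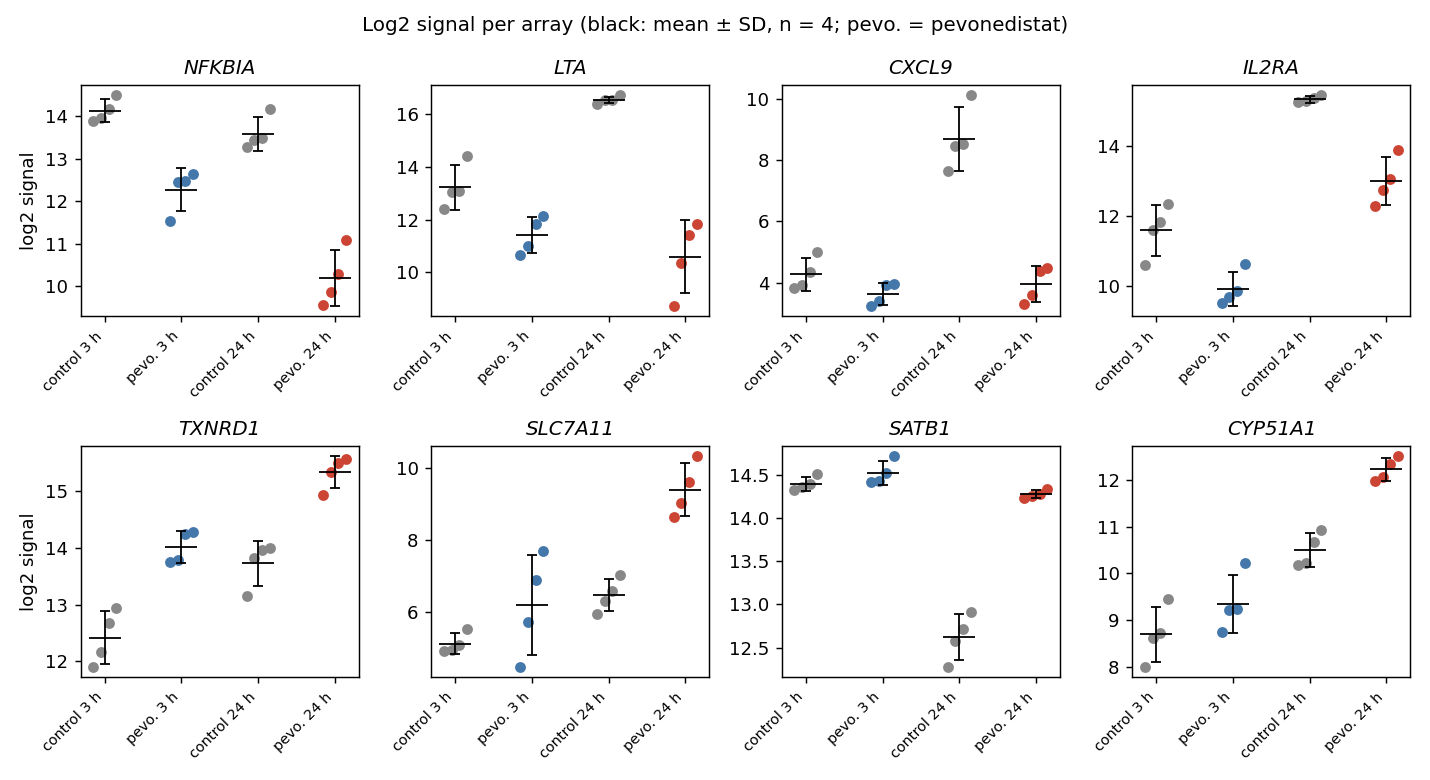
Log2 signal of 8 genes in each of the 16 arrays, with the group on the horizontal axis, points for single arrays and black bars for the mean ± SD of 4 arrays. NFKBIA and IL2RA were lower with pevonedistat in all 4 patients at both times (-1.86 and -1.67 at 3 h, -3.39 and -2.33 at 24 h), and TXNRD1 was higher by 1.60 at both.

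Transcripts of antioxidant defence, cholesterol synthesis and hypoxia response were higher as groups with pevonedistat at 24 h, though some members of the last 2 were lower. Of the NRF2 targets, 6 of 25 rose over all genes and 9 when adjusted over the list alone. The list mean was 0.810 ± 0.094 (SD over the 4 patients). Camera gave an adjusted p of 1.53e-09, and of 0.00582 with an estimated correlation. SLC7A11, the cystine importer, rose from 6.46 ± 0.45 to 9.39 ± 0.74, a 7.61-fold difference and the largest among called genes that rose in all 4 patients. OSGIN1 rose by 2.40 (SE 0.43), TALDO1 by 2.31 (SE 0.46), GSR by 1.88 (SE 0.26) and TXNRD1 by 1.60 (SE 0.26). NQO1 was at 0.50 (SE 0.41) and did not pass. Of 24 sterol biosynthesis genes 5 rose over all genes, and adjusted over the list alone 8 were higher and 1 lower. Their mean was 0.665 ± 0.069 (adjusted p = 7.05e-07, and adjusted p = 0.0122 with an estimated correlation). CYP51A1, lanosterol demethylase, rose by 1.73 (SE 0.32), ACAT2 by 1.68 (SE 0.37), HMGCS1 by 1.25 (SE 0.28) and IDI1 by 1.18 (SE 0.24). The 23 HIF-1 targets had a mean of 0.394 ± 0.111 (adjusted p = 0.00101, and adjusted p = 0.0357 with an estimated correlation). Adjusted over the list alone 7 were higher and 3 lower. Over all genes 4 rose. They were BNIP3L, up by 2.36 (SE 0.38), BNIP3, up by 1.1 (SE 0.24), both receptors of mitophagy, the MYC antagonist MXI1, up by 1.88 (SE 0.28), and the histone demethylase KDM3A, up by 1.24 (SE 0.25). ALDOC rose by 1.67 (SE 0.30), as the 1 called member of 19 glycolysis genes, a list that was not called (adjusted p = 0.744).

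Genes of the resting naive T cell were also higher with the drug at 24 h. SATB1, a chromatin organiser of naive T cells, stood at 14.28 ± 0.04 with pevonedistat and 12.62 ± 0.26 in control cells, a rise of 1.66 (SE 0.17; adjusted p = 0.0001). KLF3 rose by 1.09 (SE 0.22). The naive and quiescence list had a mean of 0.498 ± 0.170 (adjusted p = 9.91e-06, and adjusted p = 0.0369 with an estimated correlation). Of its 20 members 2 were higher over all genes and 3 adjusted over the list alone. The further large rises were those of PLXNC1, a semaphorin receptor, by 2.86 (SE 0.43), CD84, a SLAM family receptor, by 2.59 (SE 0.44), BMP2K by 2.39 (SE 0.40), DNAJC4 by 2.0 (SE 0.42), ITGA5, the integrin chain alpha 5, by 1.95 (SE 0.33) and GLIPR1 by 1.89 (SE 0.31). THEMIS, a signalling protein of developing T cells, rose by 1.86 (SE 0.37) as the 1 called member of 18 T cell identity genes, a list not called (adjusted p = 0.157).

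Genes of DNA replication and of protein turnover were lower at 24 h. The list of E2F and S phase genes had a mean of -0.887 ± 0.320 (adjusted p = 1.93e-11, and adjusted p = 0.0183 with an estimated correlation). Of 29 members 2 were lower over all genes and 14 adjusted over the list alone. The 2 were DTL, a substrate receptor of a cullin 4 ligase, which fell by 2.15 (SE 0.37), and UHRF1, a factor of DNA methylation, which fell by 1.20 (SE 0.23). MCM7 and GINS2, parts of the replicative helicase, were at -2.34 (SE 0.57) and -1.90 (SE 0.46) with adjusted p = 0.0623 and adjusted p = 0.0644, and GINS2 passed with the patient as a block (adjusted p = 0.0184). Of 28 proteasome subunits none passed over all genes and 1 was lower adjusted over the list alone, PSMC4 at -1.14 (SE 0.30; adjusted p = 0.0853, and adjusted p = 0.0499 with the patient as a block). Their mean was -0.418 ± 0.048 (adjusted p = 2.67e-08, and adjusted p = 0.00582 with an estimated correlation). Genes of ATF4 and the unfolded protein response had a mean of -0.519 ± 0.078 (adjusted p = 1.28e-06, and adjusted p = 0.0418 with an estimated correlation). None of 24 was called over all genes and 7 were lower adjusted over the list alone. Asparagine synthetase (ASNS) was at -0.96 (SE 0.30). The MYC and ribosome biogenesis list had a mean of -0.626 (adjusted p = 1.98e-09, and adjusted p = 0.0875 with an estimated correlation), and of its 25 members CAD, the first enzyme of pyrimidine synthesis, fell by 1.98 (SE 0.38). Oxidative phosphorylation genes had a mean of -0.241 (adjusted p = 0.00213, and adjusted p = 0.161 with an estimated correlation), with none of 21 called. Heat shock genes had a mean of -0.166 (adjusted p = 0.0494), which was lost with an estimated correlation (adjusted p = 0.286) and with the patient as a block (adjusted p = 0.0726). Of 25 G2/M genes none was called (list mean -0.127, adjusted p = 0.326), and MKI67 was near the lower end of the signal range, at 3.44 ± 0.41 in control cells and 3.98 ± 0.22 with pevonedistat.

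**Figure D2:**
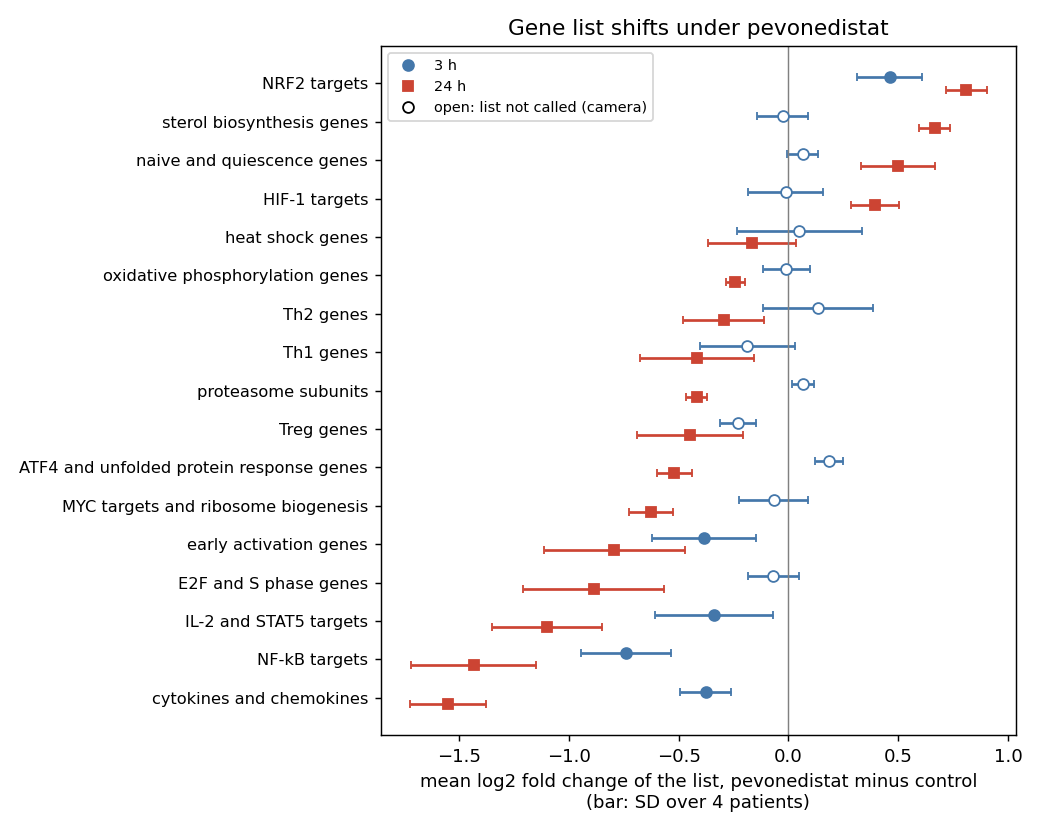
Mean log2 fold change of each gene list called at 3 h or 24 h, pevonedistat minus control, on the horizontal axis, with bars for the SD over 4 patients, circles for 3 h and squares for 24 h, and open symbols where camera with its preset correlation did not call the list. The NF-kB list stood at -0.739 at 3 h and -1.433 at 24 h, and the NRF2 list at 0.461 and 0.810.

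Of the lists of helper T cell subsets, the Treg list had a mean of -0.448 ± 0.241 (adjusted p = 0.0151, and adjusted p = 0.0461 with an estimated correlation). Its median was only -0.107, so a few members carried the mean. Of 21 members 3 were lower over all genes, IL2RA, TNFRSF4 and TGFB1, the last down by 1.56 (SE 0.28). Adjusted over the list alone 5 were lower and 1 higher. FOXP3, the lineage factor of these cells, was at 0.07 (SE 0.39). Th1 genes had a mean of -0.416 and Th2 genes of -0.295, with none of 16 members called in either, and both calls (adjusted p = 0.026 and adjusted p = 0.0394) were lost with an estimated correlation, at adjusted p = 0.226 for each. The chemokine receptor CXCR3 of the Th1 list was at -0.92 (SE 0.23, adjusted p = 0.068, and adjusted p = 0.0441 with the patient as a block) and TBX21 at -0.87 (SE 0.36). IFNG was at -1.32 with a standard error of 1.59. With the patient as a block its standard error was 0.49 (adjusted p = 0.251), and it was lower in 4 of 4 patients. GATA3 of the Th2 list was at 0.52 (SE 0.29). Th17 and Tfh genes were not called as lists, with adjusted p = 0.336 and adjusted p = 0.344. CXCR5, the follicle-homing receptor, fell by 2.53 (SE 0.39). CTLA4, an inhibitory receptor in the checkpoint list, was at 1.56 (SE 0.43; adjusted p = 0.111), and that list was not called (adjusted p = 0.326).

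The list of neddylation machinery and cullins had none of 29 members called (mean -0.071, adjusted p = 0.323), and the subunits of the enzyme that pevonedistat blocks, NAE1 and UBA3, were at 0.08 (SE 0.40) and 0.07 (SE 0.27). Of 28 substrate receptors of cullin-RING ligases, KBTBD8 fell by 2.04 (SE 0.35), while KLHL24 was at 1.88 (SE 0.60; adjusted p = 0.193, and adjusted p = 0.00614 with the patient as a block), and the list was not called (adjusted p = 0.824). The p53 list was not called (adjusted p = 0.336), with CDKN1A at -1.41 (SE 0.41; adjusted p = 0.133). FAS, a death receptor in the p53 and apoptosis lists, was at -1.53 (SE 0.40; adjusted p = 0.089, and adjusted p = 0.0372 with the patient as a block), and the nucleotide reductase subunit RRM2B at 1.32 (SE 0.37; adjusted p = 0.117, and adjusted p = 0.0421 with the patient as a block). Apoptosis regulators had 2 of 23 members lower, BCL2L1 and the death ligand TNFSF10, the latter by 1.64 (SE 0.37), and the list was not called (adjusted p = 0.0606). Of 22 interferon response genes, IFIT2 fell by 2.05 (SE 0.47), and the list was not called (adjusted p = 0.744). Of 22 replication-dependent histone genes, the linker histones H1-4 and H1-3 fell by 2.69 (SE 0.50) and 1.36 (SE 0.27). The list had an adjusted p of 0.0519, of 0.0309 with the patient as a block, and adjusted p = 0.524 with an estimated correlation. With the patient as a block more members passed at 24 h: 11 of the NF-kB list, 10 of the cytokine list and 4 of the E2F list were lower. On the same fit 7 NRF2 targets and 6 sterol genes were higher, and 2 memory markers were lower and 2 higher. Among the 4 members of smallest adjusted p in each list, those not named above that passed with the block alone included PNO1 of the ribosome biogenesis list at -1.25 (SE 0.31; adjusted p = 0.0682, blocked 0.00624), IL12RB2 of the Th1 list at -1.38 (SE 0.52; adjusted p = 0.304, blocked 0.0238) and CCL20 of the Th17 list at -2.15 (SE 0.63; adjusted p = 0.135, blocked 0.0238). On the higher side were CXCR4 of the naive list at 0.91 (SE 0.33; adjusted p = 0.269, blocked 0.0225), CD96 of the checkpoint list at 1.16 (SE 0.27; adjusted p = 0.056, blocked 0.0312), BCL11B of the T cell identity list at 0.92 (SE 0.26; adjusted p = 0.132, blocked 0.0295) and ANXA1 of the memory list at 1.69 (SE 0.73; adjusted p = 0.401, blocked 0.0118). Markers of other blood cells were not called as lists with pevonedistat at 24 h. The means were 0.053 for B cells (adjusted p = 0.839), -0.008 for monocytes and myeloid cells (adjusted p = 0.964), -0.007 for CD8 and NK cells (adjusted p = 0.964) and 0.200 for platelets and red cells (adjusted p = 0.207). Memory T cell markers had a mean of -0.001 (adjusted p = 0.807) with GPR183, a migration receptor, up by 1.22 (SE 0.28).

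Whether the effect of the drug differed between the times was tested as the difference of the effects. It was more negative at 24 h than at 3 h for CXCL9, by -4.10 (SE 0.61), SDC4, by -3.61 (SE 0.45), and CD82, by -3.10 (SE 0.49), and more positive for SATB1, by 1.53 (SE 0.25). These were the 4 genes called (adjusted p between 0.00692 and 0.0427). At 3 h CXCL9 (4.28 in control cells, 3.63 with pevonedistat) and SDC4 (5.11 and 5.0) lay below the array medians in both groups, so a fall at 3 h could hardly be measured. They stood at 8.69 and 7.89 in control cells at 24 h. With the patient as a block SATB1 and CD82 no longer passed (adjusted p = 0.0562 for both). The number of genes called fell to 1 with array weights and to 0 when the arrays of 1 patient, replicate 1 or replicate 3, were left out. Across all genes the effects at 3 h and 24 h had a Pearson correlation of 0.138 and a Spearman correlation of 0.0843. Genes are not independent replicates, so no p is given, and the comparisons share no array. Among the 98 genes lower at 24 h, 67 had a negative log2 fold change at 3 h, with a median of -0.30, and among the 61 higher genes 40 had a positive one, with a median of 0.12. Of the 98, 21 were lower at 3 h at an unadjusted p under 0.05 where 2.65 were expected for independent lists, and of the 61, 5 were higher where 1.56 were expected.

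**Figure D3:**
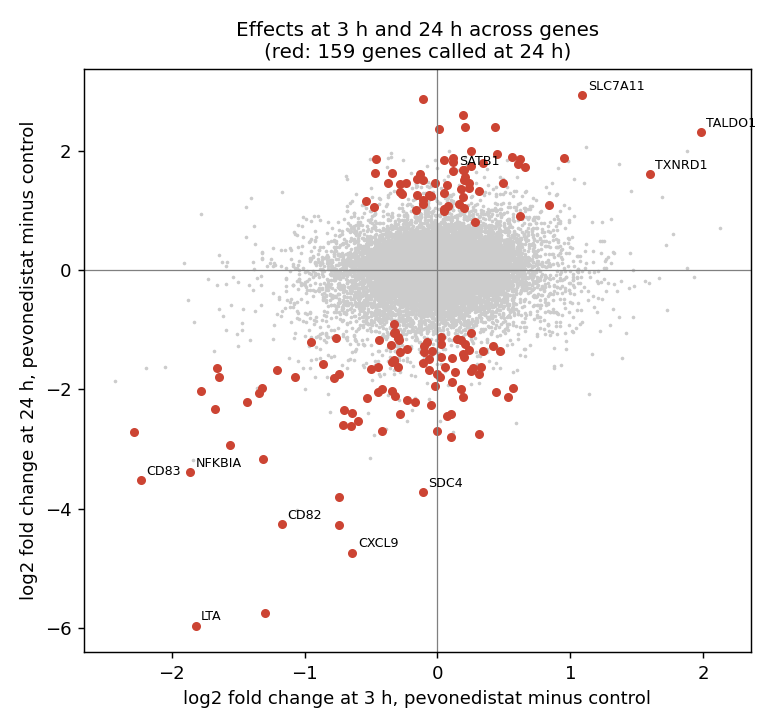
Log2 fold change with pevonedistat at 3 h (horizontal axis) and at 24 h (vertical axis), 1 point per gene, with the 159 genes called at 24 h in red. LTA (-1.82 and -5.96), CD83 and NFKBIA were low at both times, while SDC4 stood at -0.11 at 3 h and -3.72 at 24 h.

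The change between 3 h and 24 h was then examined in control cells, without drug. All arrays come from stimulated cells, so effects of stimulation and of time in culture cannot be told apart. IL2 rose between 3 h and 24 h from 7.20 ± 1.07 to 13.80 ± 0.54, a 97.3-fold difference (adjusted p = 7.47e-06). The other leading rises were the metallothionein gene MT1E by 5.38 (SE 0.36), the tryptophan tRNA ligase WARS1 by 5.28 (SE 0.31), GNG8 by 5.19 (SE 0.91) and the interferon-induced IFIT3 by 5.18 (SE 0.68). The leading falls were GAL3ST4 by 5.34 (SE 0.53), CRIP1 by 5.26 (SE 0.51), the immediate early genes FOS by 5.04 (SE 0.26) and NR4A3 by 4.68 (SE 0.30), and RASGRP2 by 4.68 (SE 0.44), the last a lower bound since it ended at 4.34, near the lower quartiles. In all 2178 genes changed, 1280 higher and 898 lower at 24 h, and 1360 were called without replicate 2.

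Proteasome subunits rose together in control cells, 25 of 28 over all genes and 27 adjusted over the list alone, with a mean of 1.388 ± 0.073. PSMD14 rose by 2.52 (SE 0.24). Genes of MYC and ribosome biogenesis (mean 1.157, 13 of 25 higher, among them WDR12 by 2.41), ATF4 and the unfolded protein response (mean 1.060, 10 of 24 higher and 1 lower, among them SHMT2 by 3.26 and ASNS by 2.69), E2F and S phase (mean 1.087, 13 of 29 higher), oxidative phosphorylation (mean 0.760, 11 of 21 higher, among them COX5A by 1.64) and glycolysis (mean 0.812, 11 of 19 higher and 1 lower, among them ENO1 by 1.88 and PGAM1 by 2.08) were called higher. So were IL-2 and STAT5 targets (mean 1.142, 8 of 24 higher, among them IL2RA by 3.74 and CISH by 5.04) and NRF2 targets (mean 0.763, 6 of 25 higher, among them TXN by 3.23). Naive and quiescence genes (mean -1.461, 13 of 20 lower), T cell identity genes (mean -0.999, 12 of 18 lower) and HIF-1 targets (mean -0.499, 7 of 23 lower and 2 higher) were called lower. Of the naive genes, KLF3 fell by 3.15, IL7R by 3.18, CXCR4 by 3.16 and SATB1 by 1.78, and of the identity genes UBASH3A by 2.17, LAT by 1.75 and CD3G by 1.71; MXI1 of the HIF-1 list fell by 2.51. These 11 lists held with an estimated correlation. The calls of 7 others were lost with it. These were cytokines and chemokines (adjusted p = 0.102), sterol biosynthesis genes, where FDPS rose by 2.43 (adjusted p = 0.102), heat shock genes (adjusted p = 0.0857) and Treg genes (adjusted p = 0.0955) on the higher side, and histone genes (adjusted p = 0.126), memory T cell markers (adjusted p = 0.245) and early activation genes (adjusted p = 0.434) on the lower side. In the last list 7 of 28 members rose and 10 fell, and EGR3 among the latter fell by 2.58. The NF-kB list was not called between the times in control cells (adjusted p = 0.255), with 4 members higher and 2 lower. TBX21 was at 1.04 (SE 0.36; adjusted p = 0.0674, and adjusted p = 0.0186 with the patient as a block), FOXP3 at 0.65 (SE 0.39), IFNG at 0.29 (SE 1.59) and MKI67 at -0.44 (SE 0.24), while GATA3 fell by 0.97 (SE 0.29). BIRC2, an inhibitor of apoptosis in the apoptosis list, fell by 3.24 (SE 0.21).

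In cells with pevonedistat 1186 genes changed between 3 h and 24 h, 580 higher and 606 lower. IL2 rose here too, by 5.61 (SE 0.68), as did TNFSF13B, also called BAFF, by 5.06 (SE 0.90), the surface enzyme CD38 by 4.72 (SE 0.78), the innate receptor TLR6 by 4.57 (SE 0.63) and the guanylate-binding protein gene GBP5 by 4.54 (SE 0.96). NR4A3 fell by 6.89 (SE 0.30), FOS by 5.55 (SE 0.26), CRIP1 by 5.34 (SE 0.51), RASGRP2 fell by 4.47 (SE 0.44) and VSIG1 fell by 4.18 (SE 0.41). The values of TLR6 (4.36 at 3 h) and RASGRP2 (4.58 at 24 h) are lower bounds, since these levels lay near the lower quartiles. Of the genes higher with time, 429 were called in both the control and the pevonedistat arrays where 42.1 were expected for independent lists, and of those lower 414 were, where 30.8 were expected. These time comparisons share no array, and their log2 fold changes had a Pearson correlation of 0.690 across genes. Proteasome subunits (mean 0.904, 14 of 28 higher) and NRF2 targets (mean 1.111, 11 of 25 higher) were again called higher, and naive and quiescence genes lower (mean -1.027, 10 of 20 lower and 1 higher). Sterol biosynthesis genes had a mean of 1.219 with 8 of 24 higher (adjusted p = 1.88e-10, and adjusted p = 0.00228 with an estimated correlation). Histone genes had a mean of -1.212 with 13 of 22 lower (adjusted p = 6.02e-15, and adjusted p = 0.0264 with an estimated correlation). With any 1 patient left out, between 595 and 773 genes were called.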

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

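The tests of slower progress, of smaller effects at 3 h and of other cells as the whole cause were chosen after the result was seen; the tests of other cells by their markers alone, of spread and of other splits of the samples were written before.

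A single array stood apart from the other 3 of its group in 20 of 335 checks, by the gap to its nearest neighbour divided by the group's range (above Dixon's 95% critical value); chance gives about 1 in 20. In control cells at 3 h these were NFKB2 (0.892), TALDO1 (0.857), CRIP1 (0.859) and FOXP3 (0.900), and with pevonedistat at 3 h KLF3 (0.831). In control cells at 24 h they were PLXNC1 (0.888), BNIP3L (0.920), IDI1 (0.849), HMGCS1 (0.852), WARS1 (0.874), IFIT3 (0.932), NQO1 (0.923), ASNS (0.917), ANXA1 (0.8359) and the NRF2 list (0.858). With pevonedistat at 24 h they were CXCR5 (0.892), CCL20 (0.922), IL2 (0.844), the NF-kB list (0.8292) and the Treg list (0.864).

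The effect of pevonedistat at 24 h differed from that at 3 h, by the test of the difference, for CD82 (-3.10), CXCL9 (-4.10), SDC4 (-3.61) and SATB1 (1.53). CXCL9 and SDC4 lay below the array medians in both groups at 3 h (4.28 and 3.63, 5.11 and 5.0), where a fall could hardly be measured. By camera with its preset correlation it differed for 15 lists. The difference was negative for cytokines and chemokines (-1.171), E2F and S phase genes (-0.818), IL-2 and STAT5 targets (-0.760), ATF4 and unfolded protein response genes (-0.703), NF-kB targets (-0.694), MYC targets and ribosome biogenesis (-0.559), proteasome subunits (-0.485), histone genes (-0.475), Th2 genes (-0.430), oxidative phosphorylation genes (-0.231) and heat shock genes (-0.216). It was positive for sterol biosynthesis genes (0.690), naive and quiescence genes (0.433), HIF-1 targets (0.405) and NRF2 targets (0.349). With an estimated correlation 1 of the 15 was called, the proteasome subunits (adjusted p = 0.043). Of 100 splits drawn, 2 called as many genes as the real one, itself included. The draws shuffled the agent labels within each time without regard to the patient. They stand for no drug effect at either time, not for an equal effect at both. So they cannot decide whether the effects differ, and they say nothing on which genes were called. The count fell to 0 without replicate 1 or replicate 3, and SATB1 and CD82 did not pass with the patient as a block (adjusted p = 0.0562 for both). The highest of the other splits called 59, which points to a structure of the samples that was not tested. Outside the genes tested, 12 array features without a gene symbol changed at 24 h, 4 higher and 8 lower, of 3689.

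NF-kB targets and cytokine genes were lower with pevonedistat at 24 h. Slower progress along a steady control time course would leave the NF-kB list between the control levels of 3 h and 24 h. The list lay below that of 3 h by -1.015 (SD 0.208, 4 of 4 patients), which argues against slower progress along such a course. For cytokine genes with IL-2 and STAT5 targets the difference was -0.11 (SD 0.282). It was -0.348 (SD 0.414, 4 of 4 patients) for the cytokines alone and 0.045 (SD 0.181) for the IL-2 and STAT5 targets alone. Each lay within 2 standard errors of 0, so slower progress stays open for these lists as wholes. Members near the lower end of the signal in control cells at 3 h, such as CXCL9 (4.28) and OSM (3.93), could hardly go lower. They hold the difference near 0, which limits this test. LTA (10.58 against 13.23), TNFSF14 (6.46 against 10.16) and LTB (9.73 against 12.47) lay far below their control level of 3 h. A loss of B, myeloid, CD8 or NK cells as the whole cause of the lower NF-kB list would need their markers to fall as far as the list, but the 9 of 50 markers above the median of all genes moved by -0.177 (SD 0.235), which is 1.257 (SD 0.44, 4 of 4 patients) above the change of the list; AIF1, the most abundant at 10.3, was at -0.01, and the sort for CD4 removes most such cells. The 9 markers were kept for their signal in the sorted cells, so which cells they come from is not known. Markers that the sorted T cells themselves express would say nothing of such a loss, and XCL1 (SE 2.01) and NKG7 (SE 0.92) were imprecise. At least a small part from such a loss stays open, since there were fewer than the 10 markers asked for and their mean was not above -0.3 by 2 standard errors.

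HIF-1 targets and naive genes, and sterol genes and NRF2 targets, were higher at 24 h. The first 2 lists together lay below their control level of 3 h by -0.504 (SD 0.048), between the control levels of the 2 times. Naive genes alone were at -0.963 (SD 0.14), so slower progress may account for them, and HIF-1 targets alone at -0.105 (SD 0.138), within 2 standard errors of their control level of 3 h, which leaves it open. Sterol genes and NRF2 targets rose with time in control cells, by 0.649 (SD 0.138) together, 0.53 (SD 0.151) and 0.763 (SD 0.209) alone, and the drug moved them further the same way. Slower progress along a steady rise forbids this, so the values argue against it for such a course. A list that peaked between 3 h and 24 h is not covered, since no array was taken in between.

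Fewer genes were called at 3 h than at 24 h. In the main fit each gene has the same standard error at both times (median 0.284). Fewer calls there mean smaller estimated differences at 3 h. A larger spread at 3 h would raise this shared standard error for both times alike, so it does not account for fewer calls at 3 h. With only the 8 arrays compared, 0 genes were called at 3 h and 181 at 24 h. The spread between patients was 1.08 times that at 24 h, which argues against a larger spread as the reason in those fits. In the NF-kB and NRF2 lists together, 2 of the 5 lists called at both times, the effect at 3 h was 0.535 times that at 24 h. The ratio lay between 0.366 and 0.875 over the patients. The effect was thus smaller at 3 h in each patient, though not in each by the margin the test asked for.

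With the pairing by patient ignored, the splits argue against chance for the genes changed at 24 h. There 1 of 35 splits, the real one, gave 159 genes and the highest other 0. The same holds for the time course in control cells (1 of 35, 2178 against 1) and with pevonedistat (1 of 35, 1186 against 2). For the number of lists at 24 h the real split came first (1 of 35, 17 against 16), with a narrow margin and a median of 6.5 over the other splits. The 7 other splits that part every pair gave up to 14 lists. For the genes at 24 h these 7 splits called at most 0. They are too few to reach 0.05 for any of these counts. So with the pairing kept, the splits cannot exclude chance for the genes at 24 h or for either time course. Chance also stays open for the number of lists. For the genes at 3 h the count of splits decides nothing, since any of the 35 splits reaches the real limma count of 0 (929 genes at an unadjusted p under 0.05, and 1 gene with the patient as a block). The highest split gave 115, and it keeps each patient's arrays together, which points to differences between patients. Chance cannot be excluded for the 5 lists at 3 h, where 9 of 35 splits gave as many and the highest other 12; the 7 other splits that part every pair gave at most 3.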

How the results depend on the processing

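No alternative was added after the data were seen. With the patient as a block 1 gene was called at 3 h and 302 at 24 h. With trend and robust settings 1 was called at 3 h and 7 for the difference of effects; with array weights 258 at 24 h (all 159 among them) and 1 for the difference. At an unadjusted p under 0.05 with a minimum fold of 2 the counts were 198 at 3 h, 651 at 24 h and 725 for the difference, and with every feature tested 8 for the difference. Leaving out 1 patient or array gave 31 to 126 genes at 24 h, 0 to 6 for the difference, 1360 to 1961 in the control time course and 595 to 1050 in that with pevonedistat. With an estimated correlation 2 lists were called at 3 h, 11 at 24 h and 11 in the control time course, and with fry 2 at 3 h. The correlation of effects was 0.552 among called genes and 0.0962 to 0.122 with 1 patient left out.

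Of 1769 values for named genes over all alternatives, 1582 kept direction and call, 141 lost the call, 36 gained it and 10 changed sign, none of the last a called gene. FOXP3 at 24 h was -0.02 with array weights and -0.26 to 0.21 with a patient left out. With a patient left out UBA3 at 24 h was -0.12 to 0.29, NAE1 at 24 h -0.03 to 0.2, NQO1 at 3 h -0.5 to 0.24, UBA3 at 3 h -0.27 to 0.02 and IFNG in the control time course -0.02 to 0.92. Of 360 values for called lists 42 lost the call and 0 changed sign.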

Other observations

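The exact permutation of list means was chosen after the data were seen; the test of the shared control arrays was written before.

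The effects of pevonedistat at 24 h ran against the time course of control cells. The log2 fold changes of the 2 comparisons correlated at -0.515 across genes, but both use the control arrays of 24 h, and simulated data with no effect gave -0.498; the covariance was -0.177, against -0.0607 in the simulated data. With the 24 h control arrays split, 2 for each comparison, the correlation lay between -0.359 and -0.274 and the covariance between -0.137 and -0.113 over 6 splits, so the shared arrays do not account for all of it. Of the genes called in both, 37 were higher with the drug and lower with time (3.1 expected for independent lists) and 67 lower with the drug and higher with time (7.11 expected). That expectation leaves out the shared arrays, which alone push genes into these 2 classes, so the counts are no evidence beyond the split arrays. A candidate explanation is that pevonedistat held back part of the change that control cells made between 3 h and 24 h. This is a hypothesis found on these data, and the NF-kB list, at -1.015 from its control level of 3 h, goes beyond a delay along a steady course. Control arrays taken at times between 3 h and 24 h would decide it: under a delay, pevonedistat cells at 24 h would match control cells of an earlier time across genes, and otherwise they would match none.

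The exact permutation of list means over 35 splits takes no account of the pairing by patient, so differences between patients count against a list. It was run only on the lists that camera had called on the same arrays, 5 at 3 h and 17 at 24 h. The adjustment covers those lists and not all 35, so a pass is no independent evidence for them. The smallest p possible is 0.0286. At 3 h the NF-kB and NRF2 lists reached it (adjusted p = 0.0715), so neither passed after adjustment in this test. At 24 h 13 of the 17 called lists reached it (adjusted p = 0.0374), and Th1 genes (0.114), Th2 genes (0.314), ATF4 and unfolded protein response genes (0.114) and heat shock genes (0.171) did not. With the patient as a block camera gave these 4 lists adjusted p = 0.00329, 0.0424, 7.96e-07 and 0.0726, and the ATF4 list was lower in 4 of 4 patients (SD 0.078 around its mean of -0.519).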
